A study of Homo sapiens with 6 samples.

How the data were processed

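RNA was taken from BeWo cells, enriched for poly(A) RNA on oligo(dT) beads and made into libraries with the NEBNext Ultra RNA kit for Illumina, per the labels' protocols. There were 6 libraries, 3 from cells given the OGT esiRNA pool (siOGT) and 3 from cells given a negative control siRNA (siCtrl). The values used were raw read counts per gene, deposited by the authors as 1 table per library. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 were used, with the genome build GRCh38. The annotation release, the strand setting and the treatment of reads that fit several places are not given in the sources used here. Reads shared by near-identical copies or by overlapping genes may therefore be lost or divided in ways that differ between genes.

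Each table held 57500 genes, and no row lacked a gene. A symbol was found for 56410 gene IDs in a table of gene names and for 56898 after GENCODE 29 names were added. Gene types, positions on GRCh38, exon lengths and transcript GC content came from the files and from GENCODE 29. Total counts ranged from 40025191 to 49113514 reads per library. A count of 3 corresponded to 0.0611 to 0.075 CPM.

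The main test was edgeR 4.0.16 (glmQLFit and glmQLFTest with robust estimation) in R 4.3.3 with group as the single term. Library sizes were scaled by TMM, and filterByExpr removed genes below a minimum count of 10 and a total of 15. This left 16286 genes. P-values were adjusted over all tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. CPM were computed with TMM effective library sizes, and SDs are over the 3 libraries of a group. The biological coefficient of variation was 3.48%. The targeted gene was also tested by a two-sided exact permutation test of its CPM in R.

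Gene lists, 34 with 1034 entries, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera was run again with the correlation estimated for each list, and fry was run as an alternative that tests whether a list's genes move, on balance, one way. The lists were O-GlcNAc cycling and hexosamine pathway, syncytiotrophoblast and fusion, cytotrophoblast and trophoblast progenitor, extravillous trophoblast, steroid hormone synthesis, nutrient transporters, mitosis and proliferation, DNA replication and E2F, p53 targets, unfolded protein response, integrated stress response, heat shock response, proteasome subunits, glycolysis, hypoxia and HIF targets, cholesterol synthesis, fatty acid synthesis and storage, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, interferon-stimulated genes, NF-kB and inflammatory genes, NRF2 targets, lysosome and autophagy, SR proteins and splicing kinases, OGT partners and Polycomb, germline genes silenced by DNA methylation, imprinted genes, YAP and TEAD targets, immediate early genes, insulin and IGF signalling, apoptosis regulators, replication-dependent histones, and markers of other cell types.

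Named genes were OGT and OGA. To these were added the 12 genes with the largest positive and the 12 with the largest negative log2 fold change among called genes of at least 5 CPM on average whose CPM did not overlap between the groups. From each list up to 4 called members with the smallest p were named. Other list members were named where they show a list's direction or exceptions to it, and were chosen after their values were seen.

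The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were other scaling factors, other filters on low counts, the replicate number as a block, removal of a trend in gene length, leaving out mitochondrial genes or each replicate in turn, DESeq2 1.42.0, limma-voom, stricter thresholds and other list tests. Removal of a GC trend, of length and GC trends together, leaving out genes with the 3′ UTR site GCAGTAC and a minimum mean of 5 CPM were added after the data were seen.

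The procedure was tested on simulated data with the means and library sizes of the real siCtrl and siOGT libraries, in 16009 genes of which 200 were changed singly and another 23, the members of a list, were all shifted upward by 1.25-fold. It recovered 74%, 84%, 96% and 100% of the 200 genes changed by 1.25, 1.5, 2 and 4-fold. It made 205 calls, 177 among the 200, 22 among the 23 list members and 6 of unchanged genes, so that 2.93% of the calls were false. The shifted list was called, and so were 2 lists that shared no member with it. The 200 genes were drawn from those with a mean count of at least 20, so the recovery does not cover genes of lower counts. Noise was drawn independently for each gene and library, which the real data need not meet. A far smaller share of genes was changed there than the 31.4% called in the real data. The recovery and the false share therefore need not carry over to the real calls.

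For the closing section, 7-base words were counted in annotated 3′ UTRs of 10757 protein-coding genes with a mean of at least 2 CPM and a 3′ UTR of at least 50 bases. Log2 fold changes were first corrected for 3′ UTR length, exon length, GC content and expression level. Each word's genes were then compared with the rest, with 1000 permutations of the fold changes over genes. The word was also picked on the odd-numbered chromosomes and tested on the others, and the reverse. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.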

Results

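Gene expression was measured by RNA sequencing in BeWo cells, a human choriocarcinoma line used as a model of placental trophoblast, after knockdown of OGT. OGT is the enzyme that attaches the sugar O-GlcNAc to serine and threonine residues of nuclear and cytoplasmic proteins. The siOGT group received a pool of enzymatically prepared siRNAs against OGT, and the siCtrl group a single non-targeting siRNA. The groups thus differ in the type of reagent as well as in OGT. For the other genes and the lists below, these libraries cannot tell an effect of the reagent from an effect of lower OGT. Cells were collected 72 h after transfection and had been kept in medium with 4.5 g/L glucose. Each group held 3 libraries of poly(A)-selected RNA, described by the series as biological replicates. Nothing further says whether they came from separate cultures or days, so the p-values measure the spread between these libraries. Total counts were 40025191, 43959486 and 49113514 reads in siCtrl replicates 1, 2 and 3 and 46559026, 42971733 and 42958174 reads in siOGT replicates 1, 2 and 3. Between 24389 and 25838 genes had at least 1 count. EEF1A1, a translation elongation factor, was the most abundant transcript in each library, with 1.19% to 1.29% of counts.

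The first principal component of log2 CPM held 38.4% of the variance and separated the groups. The second held 24.0% and set siCtrl replicate 1, with a score of 23.5, apart from siCtrl replicates 2 and 3, with scores of −19.4 and −17.7. Libraries of the same group differed by more than sampling noise in each pair, with a chi-square per degree of freedom between 1.79 and 8.26, so none was a copy of another. Pairs from different groups gave 15.2 to 20.3.

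The first question was how far the targeted transcript was lowered. OGT (ENSG00000147162, X:71533083-71575897, GRCh38, plus strand) had a normalised read count of 132 ± 5.48 CPM in siCtrl and 58.6 ± 1.22 CPM in siOGT (mean ± SD, n = 3 per group). The siCtrl libraries had 126, 134 and 137 CPM and the siOGT libraries 57.6, 58.1 and 59.9 CPM, so that OGT was lower in each siOGT library than in any siCtrl library, at 44.2% of the control level. The log2 fold change was −1.18 with a standard error of 0.037 (adjusted p = 7.12e-16, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). OGA, the enzyme that removes the same sugar, fell as well. OGA (ENSG00000198408, 10:101784443-101818465, minus strand) had 116 ± 2.64 CPM in siCtrl and 44.5 ± 1.32 CPM in siOGT (n = 3 per group), 38.2% of the control level. Its log2 fold change was −1.39 with a standard error of 0.037 (adjusted p = 3.91e-17 by the same test). For both genes a two-sided exact permutation test of the CPM gave p = 0.1, the smallest value that 3 against 3 libraries allow.

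**Figure D1:**
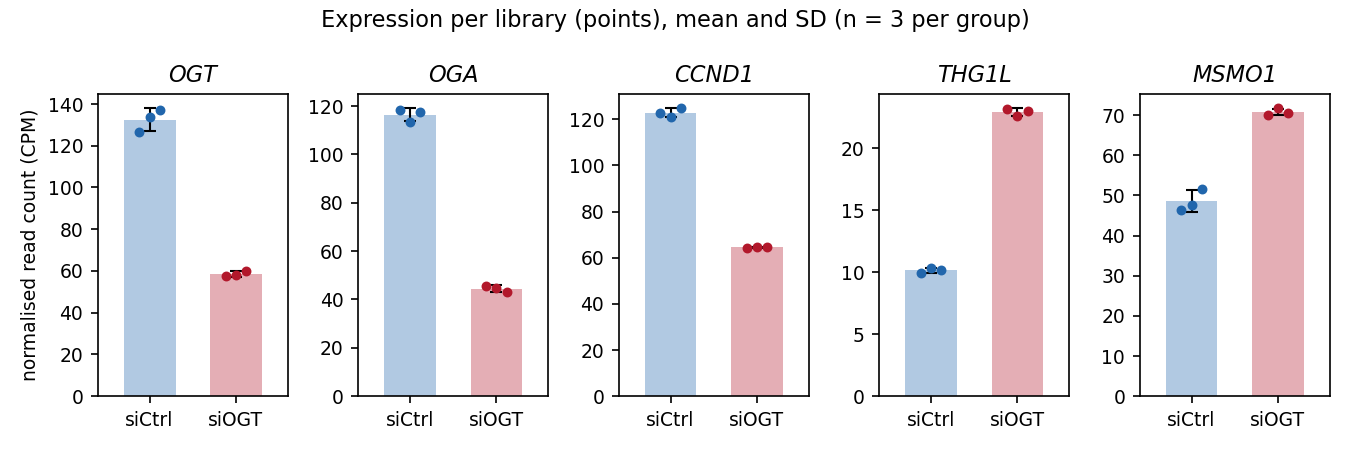
Normalised read count in CPM of OGT, OGA, CCND1, THG1L and MSMO1 in siCtrl (blue) and siOGT (red), with 1 point per library, the bar at the mean and the error bar at 1 SD (n = 3 per group). OGT fell from 132 to 58.6 CPM and OGA from 116 to 44.5 CPM, with no overlap between the groups.

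The second question was which other transcripts differed between the groups. The largest falls among called genes of at least 5 CPM without overlap between the groups, after OGA and OGT, were in MYLK3 (log2 fold change −1.08), which encodes a cardiac myosin light chain kinase, in TNFRSF11A (−0.94), the receptor RANK, and in CCND1 (−0.93), cyclin D1. CCND1 (11:69641087-69654474) fell from 123 ± 1.78 to 64.5 ± 0.185 CPM (n = 3 per group, adjusted p = 5.27e-15). MYLK, the smooth muscle counterpart of MYLK3, fell as well (−0.84). HIVEP2, a zinc finger transcription factor, fell by 0.84 on the log2 scale. The other genes among the 12 lowest were the chromatin reader ZMYND11 (−0.81), the glycine transporter SLC6A9 (−0.81), the stress-inducible GADD45B (−0.78), the phosphate transporter SLC34A2 (−0.77) and TMEM229B (−0.74).

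By the same rule, the largest rise was in THG1L, the enzyme that adds a guanosine to histidine tRNA (5:157731197-157741448), from 10.1 ± 0.193 to 22.9 ± 0.293 CPM (n = 3 per group, log2 fold change 1.18, adjusted p = 3.15e-12). KCTD17 (1.12), CNPY4 (1.11), TEX19 (1.07), a germline and placental gene, and the ephrin ligand EFNB3 (1.01) followed. The microtubule-associated FSD1 and MAPRE3 rose by 0.97 and 0.94, and SEZ6L2 by 0.95. CHPF, which takes part in chondroitin sulfate synthesis, had the highest level of these 12 genes and rose from 128 ± 10.4 to 242 ± 3.90 CPM (n = 3 per group, log2 fold change 0.93, adjusted p = 9.49e-10). The protein phosphatase subunit PPP2R5B (0.91), LYPD5 (0.89) and the myosin light chain MYL3 (0.86) completed the 12. THG1L and CHPF carry the 7-base site GCAGTAC in the 3′ UTR, as do MSMO1, LAMP2, NDUFA5, HYOU1, KIF11, PTPN14 and PAPPA among the list members named below. Genes with that site were higher in siOGT than genes without it in any part of the transcript. The log2 difference was 0.114 ± 0.01 (SE) after correction for 3′ UTR length, exon length, GC content and expression level. Before correction it was 0.072. The site was picked from these same data.

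In total 5112 of 16286 tested genes, or 31.4%, passed an adjusted p of 0.05, with 2426 higher and 2686 lower in siOGT. Most changes were small. The median log2 fold change was 0.268 among higher genes and −0.197 among lower ones, and 98 genes were higher and 39 lower by at least 2-fold. The groups did not overlap in CPM for 43.4% of tested genes, where chance alone gives 10%. The share of calls that were higher depended on the scaling: it was 47.5% here and 59.2% with upper quartile factors, which gave 3043 higher and 2097 lower genes. Without siCtrl replicate 1, the library set apart on the second component, 2679 genes were higher and 3025 lower. Lower genes had longer exon sequence than higher ones, with medians of 6418.5 and 4146 bases, and a lower median GC content, 45.3% against 52.1%.

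**Figure D2:**
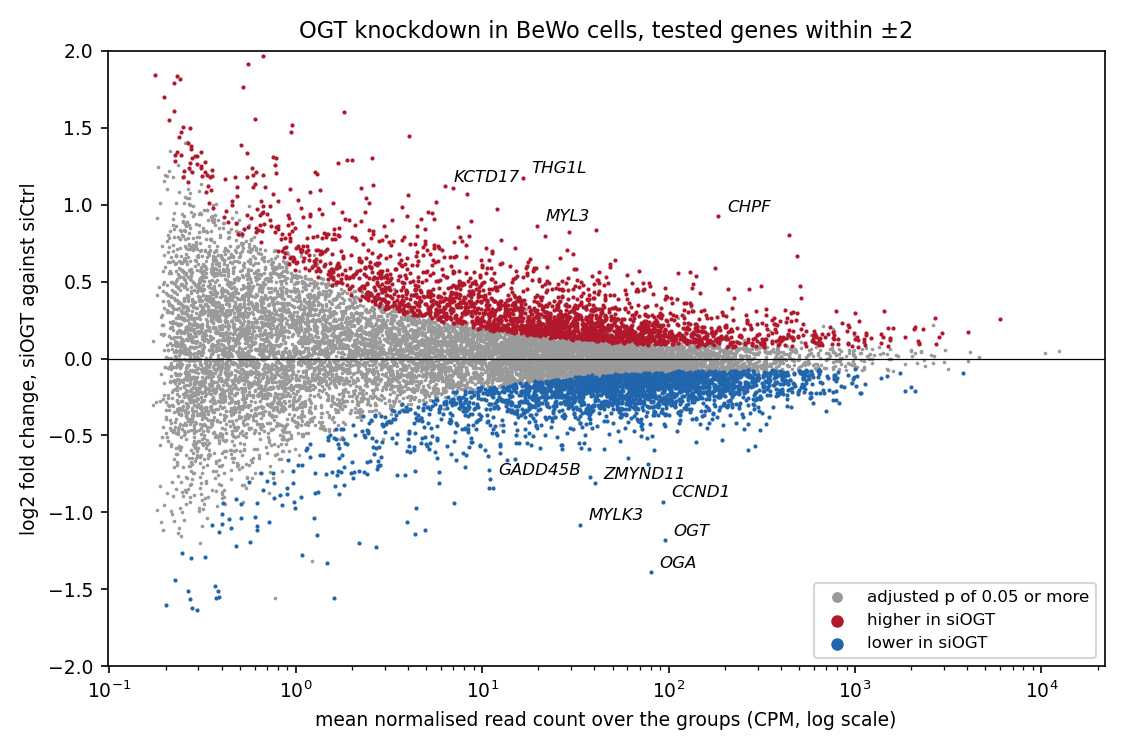
Log2 fold change of siOGT against siCtrl for each tested gene, against its mean normalised read count in CPM on a log axis, with red and blue points for genes higher and lower in siOGT at an adjusted p under 0.05 and grey points for the rest. OGA and OGT lie at −1.39 and −1.18, and 9 genes beyond 2 on either side are not drawn.

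Among 34 gene lists fixed in advance, 5 were lower and 2 were higher in siOGT by camera with a preset correlation, and none of the 7 calls held with an estimated correlation. The estimate was −0.005 for the O-GlcNAc list and −0.024 for p53 targets, under the preset 0.01, so a higher correlation did not end those calls. It was 0.012 for mitosis, 0.015 for YAP and TEAD targets, 0.022 for cholesterol synthesis, 0.039 for OGT partners and 0.355 for ribosomal proteins. Why the calls were lost was not tested. In the list of O-GlcNAc cycling and the hexosamine pathway, which supplies the sugar donor, 5 of 14 tested members fell and 0 rose, and the counts adjusted over the list alone were the same 5 and 0. Besides OGA and OGT these were GFPT1 (−0.26), the rate-limiting enzyme of the pathway, GNPDA1 (−0.17) and UAP1 (−0.18). The list was lower by its test (adjusted p = 2.79e-08; adjusted p = 0.0789 with an estimated correlation), and its median log2 fold change was −0.021. OGT, the targeted gene, is a member, so the list is not independent of the knockdown.

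Targets of the co-activator YAP and its DNA-binding partners, the TEAD factors, fell together. Of 18 tested members 13 fell and 0 rose, or 14 and 0 adjusted over the list alone, with a median of −0.204 (adjusted p = 3.54e-07; adjusted p = 0.0789 with an estimated correlation). They included CRIM1 (−0.34, from 777 ± 18.9 to 614 ± 2.61 CPM, n = 3 per group), GADD45B (−0.78), the YAP-binding phosphatase PTPN14 (−0.30), MYOF (−0.25), AJUBA (−0.23) and the kinase LATS2 (−0.17). PTPN14, AJUBA and LATS2 are known as inhibitors of YAP or of its upstream pathway as well as targets.

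Genes of mitosis and proliferation also fell, by smaller amounts. Of 30 tested members 17 fell and 1 rose, or 19 and 1 adjusted over the list alone (median −0.109, adjusted p = 0.000201; adjusted p = 0.126 with an estimated correlation). The mitotic kinase AURKA (−0.30), the topoisomerase TOP2A (−0.21), the checkpoint kinase BUB1 (−0.20) and the proliferation marker MKI67 (−0.17) fell, and the kinesin KIF11, which carries the 3′ UTR site, rose (0.17). The log2 fold changes of CDK1 (−0.07) and PLK1 (−0.04) did not pass the test. Genes of DNA replication and E2F went both ways: 8 of 39 rose and 7 fell, or 9 and 7 adjusted over the list alone (adjusted p = 0.281). The replication licensing factor CDT1 (0.33), the primase PRIM1 (0.38) and DHFR (0.39), which supplies folate for thymidylate synthesis, rose, and the repressor E2F7 fell (−0.49).

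Of 28 tested p53 targets 12 fell and 1 rose, or 12 and 2 adjusted over the list alone (median −0.055, adjusted p = 0.004; adjusted p = 0.128 with an estimated correlation). SESN2 (−0.37), the ribonucleotide reductase subunit RRM2B (−0.32), TP53INP1 (−0.33), the cell cycle inhibitor CDKN1A (−0.22) and MDM2 (−0.19), which degrades p53, fell. The list's adjusted p was 0.0712 with only genes of at least 5 CPM on average and ranged from 1.17e-05 to 0.128 over the alternatives. Of 34 tested binding partners of OGT and Polycomb genes 16 fell and 1 rose, or 17 and 1 adjusted over the list alone (median −0.079, adjusted p = 0.0158; adjusted p = 0.374 with an estimated correlation). ASXL2 (−0.24), the transcription factor SP1 (−0.19), the methyltransferase SETD1A (−0.28) and HCFC1 (−0.18), a protein that OGT cleaves, fell, as did the DNA demethylases TET1 (−0.17) and TET3 (−0.19). TET3 lost its call without siCtrl replicate 1 (adjusted p = 0.0963). RING1, a Polycomb ubiquitin ligase, rose (0.27; adjusted p = 0.0666 with length and GC trends removed), and EZH2 (0.09) did not pass. This list's adjusted p was 0.137 with the gene length trend removed and ranged from 0.000184 to 0.374 over the alternatives.

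Cholesterol synthesis genes, targets of SREBP2, rose together. Of 25 tested members 18 rose and 1 fell, with the same counts adjusted over the list alone (median 0.218, adjusted p = 2.68e-07; adjusted p = 0.0789 with an estimated correlation). MSMO1, a sterol oxidase with the 3′ UTR site GCAGTAC, rose from 48.6 ± 2.78 to 70.8 ± 0.832 CPM (n = 3 per group, log2 fold change 0.54). DHCR7, which makes cholesterol in the last step, rose by 0.44, the sterol carrier STARD4 by 0.44, FDPS by 0.24, SQLE by 0.22 and the receptor LDLR by 0.14. INSIG1, which retains SREBP in the endoplasmic reticulum and is itself an SREBP target, fell (−0.21). HMGCR (−0.05) and HMGCS1 (0.00), the early enzymes of the pathway, did not pass the test.

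Cytosolic ribosomal protein mRNAs rose slightly. Of 42 tested members 27 rose and 0 fell, or 28 and 0 adjusted over the list alone (median 0.126, adjusted p = 3.13e-07; adjusted p = 0.457 with an estimated correlation). In siCtrl replicate 1, the library set apart on the second component, 31 of the 42 were lower than in any other library: RPS18 had 901 CPM against 983 and 986 in siCtrl replicates 2 and 3, and RPLP1 730 against 821 and 799. The mean of the list was 0.123, and 0.093 without that library (adjusted p = 5.43e-08), with a range of 0.082 to 0.153 over the alternatives. RPS18 (0.24), RPLP1 (0.23) and RPS5 (0.18) rose, and RPL35 (0.19) rose but had an adjusted p of 0.578 with gene length and GC trends removed. With those trends removed, the larger adjusted p of the ribosomal protein and mitosis lists was 0.000245 at the preset correlation.

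**Figure D3:**
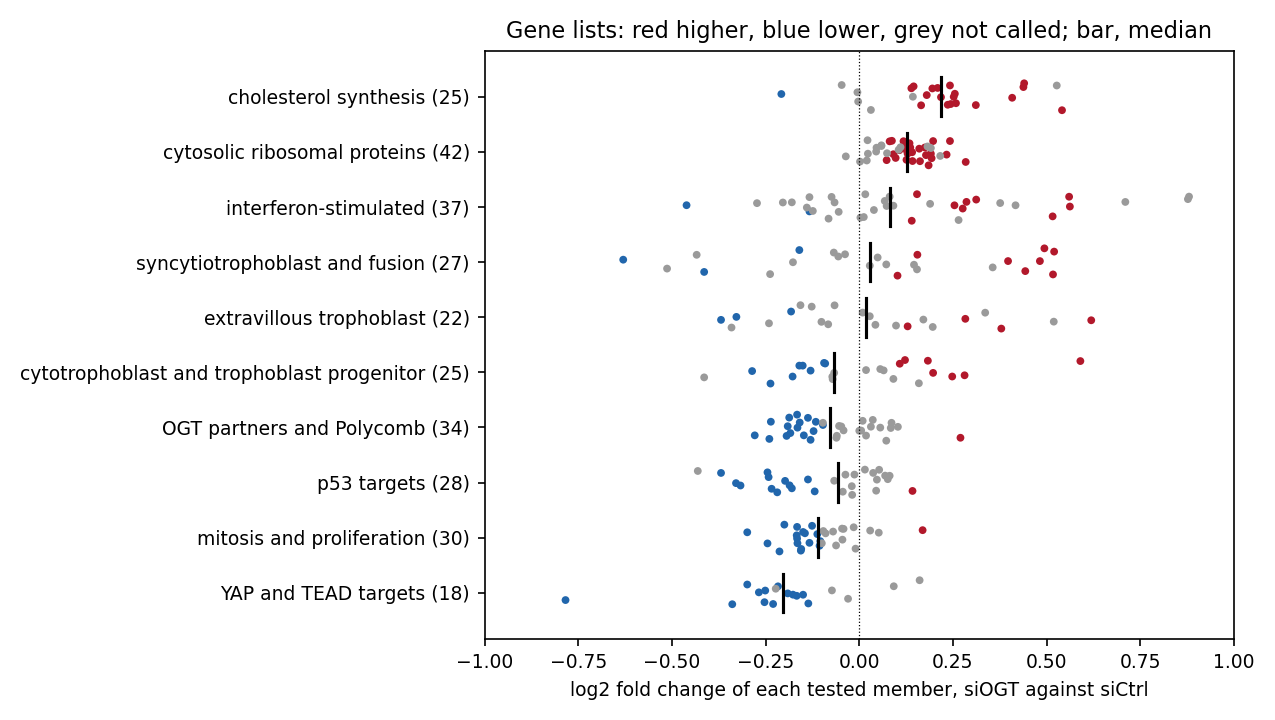
Log2 fold change of siOGT against siCtrl for each tested member of 10 gene lists, with the number of tested members in brackets, red and blue points for members higher and lower at an adjusted p under 0.05, grey points for the rest and a black bar at the median. The median was 0.218 for cholesterol synthesis and −0.204 for YAP and TEAD targets, and 5 members beyond 1 on either side are not drawn.

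The trophoblast lists went both ways and none passed camera, though fry called the extravillous trophoblast list higher (adjusted p = 0.0361). Of 27 tested genes of the syncytiotrophoblast and of fusion, 8 rose and 3 fell, or 8 and 4 adjusted over the list alone (adjusted p = 0.309). The subunits of chorionic gonadotropin CGB3 (0.52), CGB8 (0.48), CGB5 (0.44) and CGB7 (0.40), the placental growth hormone GH2 (0.49) and the retroviral envelope gene ERVV-2 (0.52) rose. CGB5 had an adjusted p of 0.0806 and CGB7 of 0.0544 with length and GC trends removed. OVOL1, a transcription factor of trophoblast differentiation, fell (−0.41), and so did the hormone gene LEP (−0.63). The shared hormone subunit CGA (0.03) and the fusion regulator GCM1 (−0.07) did not pass. The CGB genes are near-identical copies of one another, and GH2 resembles the CSH genes, so how reads were divided among them is uncertain. The median of this list was 0.028, its mean −0.196 and its test pointed up. The negative mean rested on siCtrl replicate 1, the library set apart on the second component. That library had 7.54 CPM of PAPPA, against 0.297 and 0.367 in siCtrl replicates 2 and 3, and 3.13 against 0.206 and 0.326 CPM of PSG9. It also had 2.93 against 0.388 and 0.204 CPM of PSG4 and 24.9 against 8.48 and 9.68 CPM of CSH1, and none of these 4 genes passed the test. Without siCtrl replicate 1 the mean was 0.091 (adjusted p = 0.121), and over the alternatives it ranged from −0.924 to 0.091.

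Of 25 tested cytotrophoblast and progenitor genes 7 rose and 9 fell, or 8 and 12 adjusted over the list alone (adjusted p = 0.994). PEG10 (0.59), SPINT1 (0.28), the integrin ITGB4 (0.25) and the keratin KRT7 (0.18) rose. The integrin ITGA6 (−0.18) and the transcription factors TP63 (−0.24), TEAD4 (−0.29) and GATA3 (−0.13) fell. Its median was −0.067 and its mean −0.055 while its test pointed up. Of 22 tested extravillous trophoblast genes 4 rose and 3 fell, or 5 and 4 adjusted over the list alone (adjusted p = 0.405), among them SERPINE1 (0.28), LAIR2 (0.62), SERPINE2 (0.38) and TCF7L2 (−0.18). Of 15 tested steroid hormone synthesis genes 3 rose and 2 fell, or 3 and 3 adjusted over the list alone (adjusted p = 0.912). HSD17B1, which makes estradiol, rose (0.45), as did HSD17B4 (0.27), and the sulfatase STS (−0.34) and POR (−0.26) fell. The aromatase CYP19A1 (−0.13) and CYP11A1 (−0.03) did not pass. The median of the steroid list was −0.013, its mean 0.013 (−0.004 without siCtrl replicate 3) and its test pointed down. Of 10 tested markers of other cell types 5 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.464), led by CDH5 (0.26), LIN28A (−0.30), COL1A1 (0.64) and VWF (−0.46).

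Interferon-stimulated genes lay near the threshold. Of 37 tested members 10 rose and 2 fell, or 10 and 3 adjusted over the list alone (adjusted p = 0.0535). BST2 (0.56), HERC5 (0.52), HLA-E (0.28) and IFITM3 (0.56) rose, DDX60 (−0.46) and STAT1 (−0.13) fell, and ISG15 (0.02) did not pass. The list's adjusted p was 0.0262, 0.0472, 0.02 and 0.0189 without siCtrl replicates 1, 2 and 3 and siOGT replicate 3 in turn, and ranged from 0.00129 to 0.248 over the alternatives. Of 12 tested genes of NF-kB and inflammation 2 rose and 5 fell, with the same counts adjusted over the list alone (adjusted p = 0.474). IER3 (0.39) and the adhesion molecule ICAM1 (0.49) rose, and TNFAIP2 (−0.21) and NFKB1 (−0.32) fell.

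Of 30 tested components of insulin and IGF signalling 4 rose and 12 fell, or 5 and 12 adjusted over the list alone (adjusted p = 0.0997, and 0.0499 without siCtrl replicate 2). The kinase subunits PIK3CB (−0.31) and PIK3R3 (−0.51), the phosphatase PTEN (−0.27), the receptor INSR (−0.20) and MTOR (−0.22) fell, and the translation repressor EIF4EBP1 rose (0.40). Of 34 tested genes of the integrated stress response 4 rose and 9 fell, with the same counts adjusted over the list alone (adjusted p = 0.102, and 0.0423 without siCtrl replicate 3). SLC7A1 (−0.31), XPOT (−0.29) and the serine synthesis enzyme PSAT1 (−0.30) fell with SESN2, and ASNS (0.00) did not pass. Over the alternatives the adjusted p ranged from 0.00582 to 0.471 for insulin and IGF signalling and from 0.00927 to 0.457 for the integrated stress response.

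Of 29 tested genes of the unfolded protein response 8 rose and 8 fell, or 9 and 8 adjusted over the list alone (adjusted p = 0.817). The chaperones HSP90B1 (0.26), HYOU1 (0.29), which carries the 3′ UTR site, and HSPA5 (0.14) and the secreted factor MANF (0.36) rose. The stress sensor ERN1 (−0.39), CREB3L2 (−0.43) and EDEM1 (−0.32) fell. Its median was −0.004, its mean 0.006 (−0.006 without siCtrl replicate 2) and its test pointed up. In the heat shock response 2 of 25 rose and 8 fell, or 3 and 8 adjusted over the list alone (adjusted p = 0.309), with SERPINH1 higher (0.28) and DNAJB6 (−0.21), STIP1 (−0.20) and HSPA1B (−0.29) lower. HSPA1B has a near-identical copy, so its reads are uncertain. Of 33 proteasome subunits 3 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.405), with PSME4 (−0.34), PSMD11 (−0.20) and PSMD2 (−0.18) lower. Of 21 tested NRF2 targets 1 rose and 6 fell, with the same counts adjusted over the list alone (adjusted p = 0.281). NQO1 (−0.55), TXNRD1 (−0.36) and EPHX1 (−0.27) fell and HMOX1 rose (0.21). Of 32 genes of lysosome and autophagy 12 rose and 7 fell, or 12 and 8 adjusted over the list alone (adjusted p = 0.464). LAMP2, which carries the 3′ UTR site, rose from 105 ± 5.95 to 156 ± 2.75 CPM (n = 3 per group, log2 fold change 0.56), CTSL (0.27) and HEXB (0.28) rose, and the autophagy receptor SQSTM1 (−0.43), ATP6V1B2 (−0.33) and the kinase ULK1 (−0.23) fell. Of 28 tested apoptosis regulators 2 rose and 9 fell, or 3 and 11 adjusted over the list alone (adjusted p = 0.281). APAF1 (−0.31), XIAP (−0.24) and TNFRSF10B (−0.18) fell and BAD rose (0.28), with an adjusted p of 0.191 for BAD with length and GC trends removed.

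The other metabolic lists did not pass camera, though fry called nutrient transporters lower (adjusted p = 0.0313). Of 23 tested nutrient transporters 3 rose and 8 fell, with the same counts adjusted over the list alone (adjusted p = 0.281). The glucose transporter SLC2A1 fell from 2125 ± 71.7 to 1868 ± 16.5 CPM (n = 3 per group, log2 fold change −0.19), SLC38A2 fell (−0.23), and the lactate transporter SLC16A3 (0.23) and the glutamate transporter SLC1A1 (0.47) rose. Of 23 glycolysis genes 3 rose and 9 fell, with the same counts adjusted over the list alone (adjusted p = 0.281). The hexokinase HK1 (−0.38) and PFKFB2 (−0.33) fell, the phosphofructokinase PFKM rose (0.35) and LDHA (0.01) did not pass. Of 26 tested HIF targets of the hypoxia list 4 rose and 8 fell, with the same counts adjusted over the list alone (adjusted p = 0.474), led by BNIP3L (−0.18), FAM162A (0.63) and KDM3A. The median of that list was −0.018, its mean 0.076 and its test pointed down. In fatty acid synthesis and storage 5 of 22 rose and 6 fell, or 7 and 6 adjusted over the list alone (adjusted p = 0.563), with GPAM (−0.38) and LPIN1 (−0.35) lower and ELOVL5 (0.20) and PLIN2 (0.15) higher. Of 35 nuclear-encoded respiratory chain genes 6 rose and 4 fell, with the same counts adjusted over the list alone (adjusted p = 0.281). NDUFS1 (−0.24), SDHA and NDUFA9 (−0.18) fell and NDUFA5, which carries the 3′ UTR site, rose (0.23). Of 13 mitochondrially encoded mRNAs 2 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 0.912). MT-CO1 (0.17) and MT-ND1 (0.18) rose, and MT-ATP6 (−0.13) and MT-ATP8 (−0.09), which overlap each other, fell. MT-ATP8 lost its call under 9 alternatives, among them leaving out siCtrl replicate 2 or 3 or any of the siOGT replicates (adjusted p up to 0.186).

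The remaining lists did not pass camera either, though fry called SR proteins and germline genes lower (adjusted p = 0.0177 and 0.00859). The list of SR proteins and splicing kinases also holds other splicing regulators, such as HNRNPH1. Of its 38 members 5 rose and 13 fell, with the same counts adjusted over the list alone (adjusted p = 0.283). Among them were SON (−0.23), HNRNPH1 (−0.19), SRSF1 (−0.17) and SRRM1 (−0.18). Of 31 tested immediate early genes 6 rose and 7 fell, or 6 and 8 adjusted over the list alone (adjusted p = 0.474). ETV4 (−0.56) and FOSB (−0.43) fell and ATF3 rose (0.17). Of 23 tested imprinted genes 6 rose and 6 fell, with the same counts adjusted over the list alone (adjusted p = 0.464). L3MBTL1 (0.58), the antisense transcript KCNQ1OT1 (0.51), PEG10 and H19 (0.26) rose and CMKLR2 fell (−0.50). The median was −0.009 and the mean −0.022 (0.02 without siCtrl replicate 1) while the test pointed up. Of 13 tested germline genes silenced by DNA methylation 1 rose and 3 fell, with the same counts adjusted over the list alone (adjusted p = 0.464). TEX15 rose (0.50), and TKTL1 (−1.28), TDRD1 (−0.29) and MAGEA6 (−0.18), which has a close copy in MAGEA3, fell. TKTL1 was low, at 1.54 ± 0.158 CPM in siCtrl and 0.626 ± 0.181 CPM in siOGT (n = 3 per group). It had 39, 23 and 22 reads in siOGT replicates 1, 2 and 3, and its log2 fold change ranged from −1.551 to −1.149 over the alternatives. MAGEA6 lost its call under 5 alternatives, among them leaving out siCtrl replicate 1 or 2 or siOGT replicate 1 or 3 (adjusted p up to 0.111). Of 16 tested genes of the list of replication-dependent histones 0 rose and 2 fell, or 0 and 1 adjusted over the list alone (adjusted p = 0.464). They were H1-0 (−0.22) and H2AC6 (−0.29). Most mRNAs of this list are not polyadenylated, but H1-0 also gives polyadenylated mRNA, so its fall does not speak for the class. H2AC6 lost its call under 6 alternatives, among them leaving out siCtrl replicate 3 or siOGT replicate 2 or 3 (adjusted p up to 0.203).

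Some named genes overlap expressed genes on the opposite strand, and the strand used in counting is not given in the sources used here. CNPY4, at a mean of 6.94 CPM, shares 147 exon bases with TAF6, at 45.8 CPM. CCND1, at 93.5 CPM, shares 497 exon bases with LTO1, at 8.39 CPM. HSD17B1 shares 34.8% of its exon sequence with HSD17B1-AS1, and BAD 23.7% with GPR137. DHFR, at 37.6 CPM, shares 317 exon bases with MSH3, at 40.9 CPM. PRIM1, at 36.7 CPM, shares 33 exon bases with NACA, at 805 CPM and on the same strand, which no strand setting would separate. Their values are uncertain to that extent.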

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

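The GC, length and GC, 3′ UTR site and 5 CPM alternatives were chosen after the data were seen; the others were planned. No list or followed gene that was called changed sign under any alternative. Means of several lists that were not called did, such as NF-kB (−0.155 to 0.194). With length and GC trends removed 25 of all 5112 called genes had the opposite sign, and 0 of them was called there. Of the called genes followed by name, 189 of 212 kept their call in each setting. Counts of called genes stayed within 1.5 times of 2426 higher and 2686 lower under 21 of 23 alternatives; the exceptions were stricter by construction. Requiring at least 2-fold left 98 genes higher in siOGT and 39 genes lower in siOGT, and testing against 1.2-fold with glmTreat left 318 and 188. DESeq2 called 1923 higher and 2495 lower, and limma-voom 2379 and 2631. With length and GC trends removed 79.9% of the called genes were called again. With 1 replicate left out, 1782 to 2679 genes were higher and 2064 to 3025 lower, and 2 to 3 lists were higher and 5 to 6 lower, while the OGT log2 fold change ranged from −1.21 to −1.15. With an estimated correlation camera called 0 lists higher and 0 lower, where fry called 5 and 13. Beyond the main calls, fry called extravillous trophoblast, DNA replication and E2F and interferon-stimulated genes higher. It called nutrient transporters, the integrated stress and heat shock responses and NRF2 targets lower. SR proteins, germline genes, insulin and IGF signalling and apoptosis regulators were lower by fry as well. Each of the 7 list calls held under the 3 other scalings. A scaling shifts all genes nearly alike, and camera compares a list with the other genes, so this tests the calls little. With a mean of at least 5 CPM 3 lists were lower: the lists of p53 targets and OGT partners lost their call, and the cause was not tested. The replicate block gave 2409 higher and 2712 lower genes and the same number of lists. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at −0.097, −0.043 and −0.04, and not every library correlated best with its own number. At these depths a count of 3 is 0.0611 to 0.075 CPM, which limits what can be said of genes near that level.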

Other observations

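The scan of 3′ UTR words, the test of GC bias between libraries, the tests of the site and the choice of the genes named in this part were made after results were seen. Several genes outside the rule for named genes rose. TLN1, which links integrins to actin, rose from 323 ± 5.69 to 564 ± 8.23 CPM (mean ± SD, n = 3 per group, log2 fold change 0.80, adjusted p = 5.27e-15). The basement membrane gene NID1 rose from 375 ± 7.88 to 596 ± 2.02 CPM (log2 fold change 0.67, adjusted p = 1.02e-13). IL6ST, the shared receptor subunit of the interleukin 6 family, rose by 0.47. These genes carry the 3′ UTR site GCAGTAC. The annexin ANXA6 rose by 0.48, the lysosomal acid lipase LIPA by 0.59 and the muscle genes TNNT1 and ACTA1 by 0.64 and 0.71. DNMT3L, a cofactor of DNA methylation, rose by 0.49 and the maintenance methyltransferase DNMT1, which also carries the site, by 0.28.

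Among called non-coding genes more were higher than lower, and whether this differs from protein-coding genes was not tested. Of 980 tested antisense genes 71 were higher and 26 lower, and of 750 lincRNAs 52 were higher and 33 lower. Among 416 processed pseudogenes 17 were higher and 5 lower, against 2192 higher and 2598 lower among 13013 protein-coding genes. Without a stated strand, antisense counts cannot be separated from those of their partners.

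Genes that rose were rich in the 7-base word GCAGTAC in the 3′ UTR. Of 16380 words it stood first among higher ones, with 574 genes and z = 13.1 after correction for length, GC and expression level. The highest absolute z in 1000 permutations was 5.61 (p = 0.001, the smallest they can give). Before correction the word also stood first on that side, with z = 7.80, while words on the lower side reached −19.72. Of the 20 scanned genes with the smallest p among the higher ones, 13 carried it, or 65.0% against 5.3% of all scanned genes, led by TLN1, NID1, THG1L, SLC41A1 (0.84), XPR1 (0.59) and NUDT15 (0.82). The share was 46.0% among the 50 and 36.0% among the 100 higher genes with the smallest p. Of 130 scanned genes called higher by at least 1.5-fold, 19 carried it, or 14.6%. Of the 574 genes with the site 34.3% were called higher and 16.7% lower, against 16.8% and 24.1% of genes with no site. Among the 20 with the smallest p on the lower side 1 carried it.

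A length or GC trend is argued against as its cause, since the trends alone give a log2 difference of −0.042 ± 0.002 (SE) between genes with and without the site, where the uncorrected difference was 0.072. Seed-guided repression by a short RNA that differs between the groups is a candidate explanation: picked on the odd or on the other chromosomes the word was the same, and on those left out 3′ UTR sites exceeded sites in the coding part alone by 0.057 ± 0.016 and 0.094 ± 0.016 (SE). Sites in the coding part alone were themselves above no site, by 0.045 ± 0.009 and 0.031 ± 0.008 there. The site genes may be lowered by the single-sequence control siRNA rather than raised by loss of OGT, but with 1 control reagent these sources cannot be told apart, because reagent and group divide the libraries the same way. If so, the rises of TLN1, NID1, THG1L, CHPF and MSMO1 may reflect the control, which a second control reagent or untreated cells would show.

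Long and low-GC genes were lower in siOGT, with a Spearman rho across genes of −0.241 between log2 fold change and exon length and 0.195 with GC content; genes are not independent replicates. Length bias that varies from library to library is argued against, as the nearest slopes of the groups were 0.0306 apart on the log2 scale per doubling of length and ranged by at most 0.0147 within a group. For GC the gap of 0.0009 per 10 points was far within the range of 0.0668 inside a group, so GC bias between libraries may account for that part. The trends were not the whole cause of the ribosomal protein and mitosis calls at the preset correlation, where their larger adjusted p was 0.000245 with both removed (edgeR and camera); without that removal both calls were lost with an estimated correlation (adjusted p = 0.457 and 0.126). A length bias tied to the group and a response to the loss of OGT both remain open and were not tested.

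OGA fell together with OGT, although the reagent was directed at OGT. Direct cleavage of OGA mRNA through an exact shared stretch of at least 16 bases, the length set as a minimum, is argued against. Over 11 annotated transcripts of each gene the longest exact stretch in common was 14 bases. The median of genes as long as OGA was also 14. Effects of the reagent on OGA through shorter or mismatched stretches were not tested. CCND1 and MYLK3 each share 16 bases with OGT, at that minimum though under the 95th percentile of 21 for genes as long as OGA, so cleavage is not excluded for them. A response of OGA expression to lower OGT remains a hypothesis that these libraries do not test further.

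The calls were also counted for other splits of the libraries. There are 10 ways to divide the 6 libraries into groups of 3, too few for a share under 0.05. The real split gave 5112 called genes and the highest of the others 0; for lists the real split gave 7 and the highest other 5. In each case 1 split, the real one, reached the real value. Each other split mixes siCtrl and siOGT libraries in both of its groups, so the difference between the conditions adds to the spread within them. The other splits therefore do not show how many calls chance alone would give.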
